A study of Mus musculus with 6 samples.

How the data were processed

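The data were RNA sequencing counts from 6 mouse neocortex libraries at embryonic day 18.5, 3 labelled Tshz3 mutant and 3 wild type, each from a separate pool of 3 to 4 embryos, per the labels. Libraries were made with a stranded TruSeq kit, per the labels' protocols. The table the authors deposited holds raw counts of reads per gene symbol, whole numbers with no normalization. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.9, Bowtie2 2.1.0 and HTSeq 0.5.3p9 and the genome build mm10. Their roles, order and settings, the gene annotation and the strand setting of the counting are not given in the sources used here. Overlapping or antisense genes, near-identical gene copies and transcripts lying inside other genes could therefore share or lose reads, and such genes are named as uncertain. All rows named a gene, and 0 columns of sample values were left unused.

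Columns were assigned to libraries by their names, which are the sample titles, and each library's group came from its label. Total counts ran from 18569383 to 24147810 per library, so depth differed little. Same-genotype libraries differed by more than sampling noise, with a chi-square per degree of freedom of 7.13 to 23.1 over genes with at least 20 counts in total, and no library was a copy of another. The pools came from multiple litters, so p-values reflect the spread between pools of animals.

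Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersion, TMM scaling and default expression filtering, two-sided, and Benjamini-Hochberg adjustment over 14618 genes with a threshold of 0.05. Standard errors were derived from the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes, and the SD is over 3 libraries. The fit was run without pairing, as chosen before the data were examined, and again with the library number as a block.

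Pairing was checked from the correlation across genes of the libraries' deviations from their group means, before the calls of the fits were compared. Same-numbered libraries correlated at 0.61, 0.51 and 0.47, and the other combinations at −0.48 to −0.07. Deviations from a group mean cancel out within the group, so positive values for same-numbered libraries push the others down. The negative values are thus no separate evidence for pairing. For the same reason the 3 positive values are not independent, and with 3 libraries per group they could arise without true pairs. The first 3 principal components held 36.8%, 28.3% and 18.1% of the variance. All 3 pairs passed the bound of 0.1 set beforehand, so the numbers were taken to pair the libraries and blocked values are given beside the others. The pairing comes from the data, because the labels give the numbers without saying what they share. The biological coefficient of variation was 0.128 without the block and 0.0584 with it.

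The fits were tested on simulated data for this comparison, with 200 changed genes drawn into counts for 14507 genes on average over 3 draws. Without the block, 9.33% of genes changed 1.3-fold and 79% of genes changed 2-fold were recovered. With it, 71% and 99.7% were. False calls averaged 0 of 88.3 without the block and 9.67 of 180 with it. The simulated counts held pair effects and used the dispersion of the fit with the block. These rates therefore favour the block and cannot show how it behaves if the numbers mark no pairs. In 3 simulated draws with a raised gene list, the blocked list test with an estimated correlation called the list in 0 of 3 and every other list test run called it in 3 of 3, so that test had low power in these draws. Apart from pair effects, genes were drawn independently. The list results therefore do not carry over to lists whose members move together, such as cell division genes, with an estimated correlation of 0.81 without the block.

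Gene lists were fixed before the data were examined: 32 lists of 672 names in all, of which 639 were found in the table, 9 of them through an older symbol, and 33 were not. They covered the Tshz family, neocortical neuron classes, progenitors, cell division, interneurons, neighbouring brain regions, glia, vessels, meninges, microglia, blood, synapse, axon guidance, autism, activity, hypoxia, cholesterol, potassium channel, ribosomal protein, histone and sex-linked genes and neighbours of Tshz3. The list of mitochondrially encoded transcripts had no member in the table, so 31 lists were tested. List tests used limma 3.58.1 on log2 CPM with a prior count of 2. Camera, which compares a list with the other tested genes, was run with a preset correlation of 0.01 and with an estimated one, and fry, which tests whether a list's genes move without comparing them with other genes, was run beside it.

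Named genes followed a rule set before the data were examined. It took the 3 Tshz genes, up to 12 genes per direction with the largest change among called genes with mean log2 CPM of at least 1 and no overlap between groups, skipping gene models without a proper symbol, up to 4 members of each list by p-value, and layer identity transcription factors, of which Bcl11b, Fezf2, Tbr1, Cux2 and Foxp2 are given. Some genes that the rule takes are not reported here. From the lists, members that passed singly were named and the others sparingly. Applying the rule to the paired fit was decided after the data were seen. Genes outside the rule were named after their values were seen, namely A930011O12Rik, 1600014C10Rik, Gm20594, Syt6, Sv2b, Draxin, Epha3, Epha5, Auts2, Shank2, Fos and Fosb, the small or long RNAs Mir17hg, A330023F24Rik, Mirlet7b, Mirlet7c-2, Mir3064, Malat1, Neat1 and Meg3, and Dgcr8, Ntrk2, Ntrk3, Ntsr1, Wnt2, Wnt7b, Bhlhe22, Prdm8, Sstr1, Timp3 and Gpi1.

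Alternatives were DESeq2 1.42.0 as the test, limma-voom, DESeq2 and upper-quartile scaling, no filter, a stricter filter of 1 CPM in 3 libraries, a log2 fold threshold of 0.5, counts thinned to the smallest library, leaving out haemoglobin genes, each library left out, and the block. Settings chosen after the data were seen were leaving out 2 single-sex pools, Y-linked CPM as a covariate, and the same alternatives for the paired fit, including each pair left out. Mitochondrial genes could not be left out, since none was found. Positions and gene types come from GENCODE release M21 on GRCm38, the assembly also called mm10, with 21777 of 23420 symbols matched directly, 1277 through an older symbol, and 23011 given a single position. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.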

Results

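The study measured gene expression by RNA sequencing in the neocortex of mouse embryos at embryonic day 18.5. It compared embryos labelled as mutant for Tshz3, a gene encoding a zinc finger transcription factor of the teashirt family, with wild-type embryos. Each genotype had 3 libraries, and each library was made from a separate pool of cortices from 3 to 4 embryos. Total gene counts were 20836732, 24147810 and 19894144 in mutant libraries 1, 2 and 3, and 21052832, 20772628 and 18569383 in wild-type libraries 1, 2 and 3. Of 23420 genes in the deposited table, 4515 had no read in any library and 14618 were tested. The single comparison of the design asks which transcripts differ between the genotypes, and fold changes below are mutant-labelled over wild type.

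Tshz3 transcript was not lower in the mutant-labelled libraries. Tshz3 spans positions 36698118 to 36773553 of chromosome 7 on the plus strand of GRCm38. Its normalised level was 89.8, 93.1 and 99.2 CPM, a count scaled to library size, in mutant libraries 1 to 3, against 78.7, 83.0 and 89.3 CPM in wild-type libraries 1 to 3. Each mutant library thus lay above each wild-type library, though by as little as 89.8 against 89.3 CPM. Chance sets 3 against 3 libraries apart, in either direction, for 10% of unselected genes. The log2 fold change of Tshz3 was 0.17 (SE 0.07, n = 3 per group), with an edgeR adjusted p of 0.669, or 0.0525 when libraries were paired by number. Which part of Tshz3 was mutated is not given in the sources used here, and the table holds 1 count per gene. The gene-level count therefore did not check the genotype labels, and the libraries are called mutant-labelled throughout. Among the related genes, Tshz2 was 37.3 ± 2.12 CPM (SD, n = 3) in mutant-labelled libraries and 29.1 ± 2.01 CPM in wild type, a log2 fold change of 0.36 with adjusted p = 0.283 unpaired and 0.0156 paired. Tshz1 had a log2 fold change of 0.08 (SE 0.09) and passed neither test.

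Egr1, an immediate-early transcription factor induced by neuronal activity, had the largest drop among genes past the threshold without pairing. It fell from 50.8 ± 2.64 CPM in wild type to 14.2 ± 1.31 CPM in mutant-labelled libraries (SD, n = 3 each), a log2 fold change of −1.84 (SE 0.09, edgeR adjusted p = 0.000586). Hs3st4, a heparan sulfate sulfotransferase enriched in deep-layer cortical neurons, fell by 0.73 on the log2 scale (SE 0.08, adjusted p = 0.0317), and Stac2 fell by 0.59 (SE 0.07, adjusted p = 0.0417). The secreted growth factor Fgf10 rose 2.74-fold, from 6.14 ± 0.753 to 16.8 ± 1.04 CPM (adjusted p = 0.00804). The tight junction gene Cldn1 rose 2.58-fold and Trhr, the receptor for thyrotropin-releasing hormone, rose 2.59-fold.

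Sertm1, a small transmembrane protein gene, rose 2.03-fold with little spread, from 35.2 ± 1.23 to 71.5 ± 2.5 CPM (log2 fold change 1.02, SE 0.06, adjusted p = 0.00119). Rspo2, a secreted enhancer of Wnt signalling, rose 1.76-fold (adjusted p = 0.03). The non-coding transcript A930011O12Rik, annotated as Mir124a-1hg because it holds the microRNA gene Mir124a-1, rose from 193 ± 28.4 to 457 ± 10.7 CPM (log2 fold change 1.25, SE 0.10, adjusted p = 0.00787). The open reading frame 1600014C10Rik rose 1.65-fold. Gm20594, also named Mtrnr2l after its likeness to a mitochondrial ribosomal RNA, fell by 1.26 on the log2 scale (SE 0.08), and its count is uncertain because mitochondrial reads could be assigned to it.

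These 7 higher and 4 lower genes were all that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test without pairing, and 1037 genes had an unadjusted p under 0.05. DESeq2 called 63 higher and 43 lower on the same counts, among them all 11. The count depended on single libraries: it was 21 higher and 14 lower without wild type 2, and between 3 and 7 genes in all without any 1 of the other 5 libraries. Egr1, Sertm1 and Gm20594 passed in each of those 6 fits.

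On GRCm38, Egr1 lies on chromosome 18 from 34859823 to 34864984, Stac2 on chromosome 11 from 98036623 to 98053462, and Gm20594 on chromosome 6 from 79817916 to 79818364. Hs3st4 lies on chromosome 7 from 123982869 to 124398989, and 1600014C10Rik on the same chromosome from 38183217 to 38197568, near Tshz3. Fgf10 lies on chromosome 13 from 118669791 to 118792115, Cldn1 on chromosome 16 from 26356642 to 26371841 and Sertm1 on chromosome 3 from 54897068 to 54915887. Trhr and Rspo2 are both on chromosome 15, from 44196135 to 44235912 and from 43020794 to 43170826. A930011O12Rik lies on chromosome 14 from 64587331 to 64593961. Each interval is the whole annotated gene, exons and introns together, and the counts cover the gene as 1 unit.

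**Figure D1:**
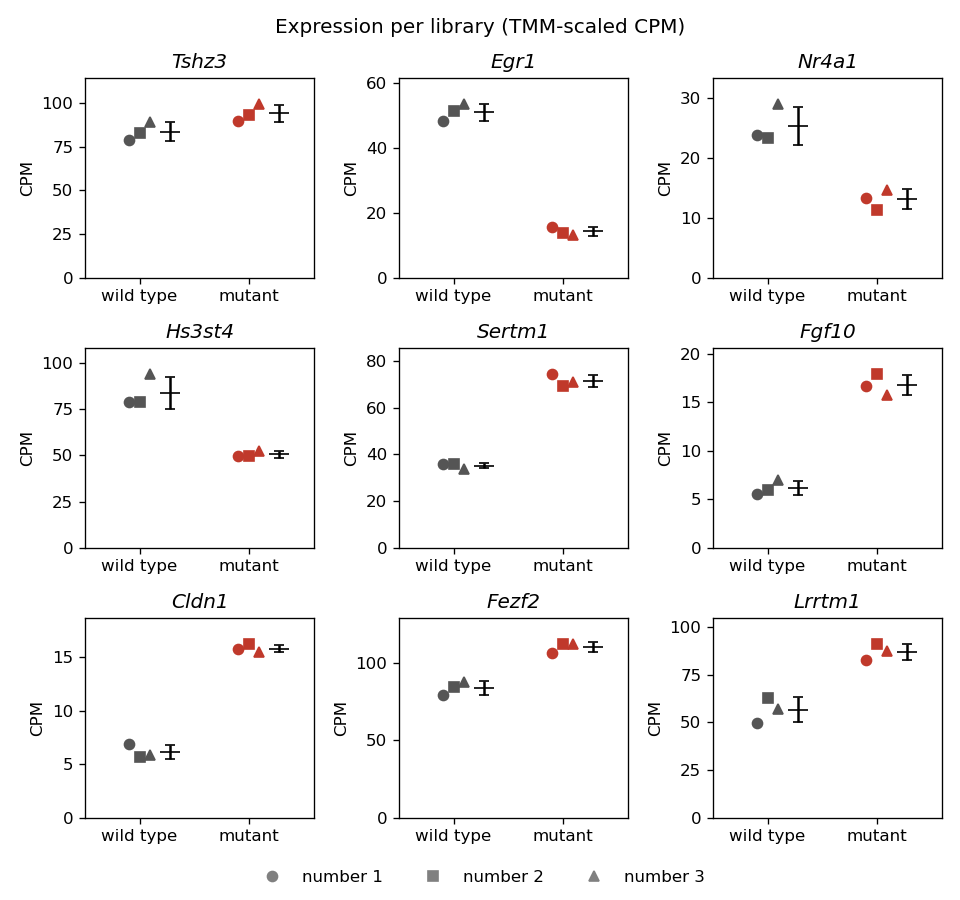
Normalised expression (CPM, linear axis from 0) of 9 genes in each of the 6 libraries, with wild type in grey and mutant-labelled in red, symbols giving the library number, and the bar at the right of each group the mean ± SD of 3 libraries. Egr1, Nr4a1 and Hs3st4 were lower in every mutant-labelled library than in any wild-type library, and Sertm1, Fgf10, Cldn1, Fezf2 and Lrrtm1 were higher in every one. Tshz3 was also higher in every one, by a small margin, and did not pass with or without pairing.

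Libraries with the same number deviated together from their group means, which is why paired values stand beside the unpaired ones. Such a match could also arise by chance with 3 libraries per group, and the labels do not state pairs. With the number as a block, 288 genes were higher and 218 lower in mutant-labelled libraries, including all 11 above. Most changes were small, with a median absolute log2 fold change of 0.33 among the higher and 0.34 among the lower genes, and 66 and 67 genes reached 0.5. All 506 kept 1 sign in the 3 pairs, and in 213 of the higher and 155 of the lower genes every mutant-labelled library lay beyond every wild-type library, where chance gives 10% for an unselected gene in 3 against 3. These genes were picked by the paired test, so that share is no reference for them. The paired count rested strongly on single pairs, with 35 higher and 27 lower genes without pair 3 and 1119 higher and 755 lower without pair 2. Each pair left out leaves 1 residual degree of freedom. Genes named below passed only with pairing unless the text says otherwise.

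**Figure D2:**
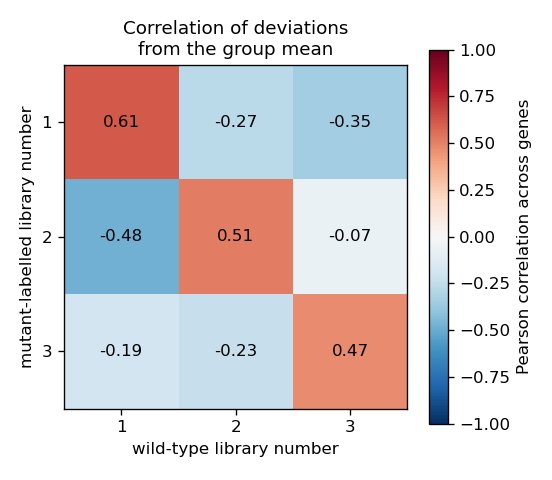
Pearson correlation across genes of each mutant-labelled library's deviation from its group mean (rows) with each wild-type library's deviation (columns). The correlations of same-numbered libraries were 0.61, 0.51 and 0.47, and all others lay between −0.48 and −0.07.

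Among genes with a proper symbol, a mean log2 CPM of at least 1 and no overlap between groups, the largest paired increases besides Fgf10, Trhr, Cldn1 and Sertm1 were in Samd9l, Hs3st3b1, Scube2, Trpc7, Acvr1c, Zfp599 and the small nucleolar RNAs Snord47 and Snora61. Samd9l rose by 1.62 on the log2 scale (SE 0.21, adjusted p = 0.000503) from a low level of 1.22 ± 0.28 CPM. Hs3st3b1, which encodes another heparan sulfate sulfotransferase, rose by 1.09 (SE 0.17, adjusted p = 0.00261). The cation channel gene Trpc7 had a paired log2 fold change of 0.97 and the activin receptor gene Acvr1c one of 0.93. Snord47 and Snora61 lie inside the host genes Gas5 and Snhg12, so their counts are uncertain.

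Within the same limits, the largest paired decreases after Egr1 were in Ipw, Hist1h1c, Ngfr, Gprin2, Hist1h2bc, Nr4a1, Col23a1, Klf4, Ramp3, Itgb1bp2 and Kcns1. Ipw, a non-coding transcript of the imprinted Prader-Willi region, fell by 1.37 (SE 0.11, adjusted p = 1.68e-05), from 26.8 ± 5.83 to 10.5 ± 3.28 CPM. Ngfr, the p75 neurotrophin receptor gene, fell by 1.24 (SE 0.15, adjusted p = 0.000352). Nr4a1, an immediate-early nuclear receptor gene, fell by 0.95 (SE 0.09, adjusted p = 2e-05), and the collagen gene Col23a1 by 0.95 (SE 0.09). Klf4, a zinc finger transcription factor gene, fell by 0.85 (SE 0.14), and the potassium channel subunit gene Kcns1 by 0.77 (SE 0.16).

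Markers of deep-layer projection neurons moved in both directions. Of 21 tested, the paired fit called 3 higher and 3 lower, and 15 did not pass; adjusted over the list alone, the counts were 5 and 7. Fezf2, which specifies subcortical projection neurons, rose by 0.40 on the log2 scale (SE 0.04, adjusted p = 0.000158), from 83.6 ± 4.37 to 110 ± 3.1 CPM. Ldb2 rose by 0.35 (SE 0.04) and Bcl11b, also known as Ctip2, by 0.15 (SE 0.04, adjusted p = 0.0478). Hs3st4, Dkk3 and Syt6 fell by 0.73, 0.34 and 0.23. Without pairing only Hs3st4 passed, or 3 higher and 2 lower genes adjusted over the list alone. Tbr1, which marks early corticothalamic neurons, had a log2 fold change of 0.02 (SE 0.08) whose sign changed when single libraries were left out, and Foxp2 one of −0.15 (SE 0.08). As a list the deep-layer markers did not pass camera, with adjusted p = 0.57 both unpaired and paired. For them fry's test for change in either direction passed (adjusted p = 0.00022, paired 0.004). When paired, that test passed 22 of the 31 lists tested, so the paired pass was not particular to deep-layer markers.

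Among 20 upper-layer markers the paired fit called 3 higher, 0 lower and 17 not past the threshold, with 3 higher and 2 lower adjusted over the list alone. Among them, the transcription factor gene Pou3f1 rose by 0.29 (SE 0.05, adjusted p = 0.00547) and Mdga1 by 0.23 (SE 0.04, adjusted p = 0.00746). Cux2 had an unpaired log2 fold change of 0.13 (SE 0.17) with no steady sign when single libraries were left out. Of 14 subplate markers, Pde1a rose by 0.28 and Cplx3, a marker at only 0.911 ± 0.173 CPM in wild type, fell by 2.28 (SE 0.44), with 2 higher and 2 lower adjusted over the list alone. Of 12 Cajal-Retzius markers, Spock1 fell by 0.24 (SE 0.04), with 2 lower adjusted over the list alone. Paired, fry's test for change in either direction passed all 3 of these lists (adjusted p = 0.019, 0.019 and 0.032). On all 6 libraries none of them passed camera, with paired adjusted p = 0.31, 0.22 and 0.53. The subplate list passed camera downward, unpaired, without mutant 1 (0.042).

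Of 20 activity-induced genes tested, the paired fit called Egr1, Nr4a1, Ier2, Egr2 and Fosb lower and none higher, and 15 did not pass; adjusted over the list alone, 10 were lower and 1 higher. The list passed camera with a preset correlation (adjusted p = 2.2e-08, paired 8e-05), unpaired also without any 1 library, but not with an estimated correlation (adjusted p = 0.81, paired 0.65) or with fry's test of movement in 1 direction (adjusted p = 0.13, paired also 0.13). Ier2 fell by 0.70 (SE 0.11), Egr2 by 1.78 (SE 0.29) and Fosb by 1.51 (SE 0.30), the last 2 from levels of 1.71 ± 0.45 and 1.56 ± 0.311 CPM. Fos itself had a paired log2 fold change of −1.71 with adjusted p = 0.112. Without pairing Egr1 alone passed, or 8 lower genes adjusted over the list alone. The list median was −0.45, and −0.17, −0.73 and −0.55 within pairs 1, 2 and 3.

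Among 11 intermediate progenitor markers, the paired fit called the proneural gene Neurog2 higher by 0.46 (SE 0.10) and Elavl4 higher by 0.28 (SE 0.05), with 3 higher adjusted over the list alone. None of 17 radial glia markers passed, Hes1 having a paired log2 fold change of −0.62 (SE 0.25). Of 20 cortical interneuron markers, Cxcr4, a chemokine receptor of migrating interneurons, rose by 0.47 (SE 0.07) and Sp8 by 0.43 (SE 0.11), while the neuropeptide gene Npy fell by 0.41 (SE 0.05). Adjusted over the list alone, 2 interneuron markers were higher and 5 lower. These 3 lists did not pass camera, with paired adjusted p = 0.54, 0.58 and 0.70. Paired, fry's test for change in either direction passed the progenitor and interneuron lists (adjusted p = 0.021 and 0.0015), not the radial glia list (0.17). The progenitor list had a median of −0.05 and a mean of 0.05, and the radial glia list a median of 0 and a mean of −0.03, while camera put both in the upward direction.

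Of 25 cell division genes none passed singly in either fit, and Kif20a and Aurka had paired log2 fold changes of 0.33 and 0.29. The list median was 0.12, and the list passed camera with the preset correlation (adjusted p = 0.010, paired 6.2e-05) but had adjusted p = 0.91 with an estimated correlation, paired 0.65. The unpaired camera call rested on single libraries, with adjusted p = 0.53 without mutant 1, 0.11 without wild type 2 and 0.43 without wild type 3. It held without mutant 2 (0.03), mutant 3 (2.8e-07), wild type 1 (1.6e-05) or mutant 3 and wild type 1 together (7.4e-12).

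Synapse genes showed a few single changes. Of 30 postsynaptic glutamatergic genes, Lrrtm1, a synaptic adhesion gene, rose by 0.62 (SE 0.05, adjusted p = 1.11e-05), from 56.6 ± 6.55 to 87.1 ± 4.24 CPM. Shank2, which encodes a scaffold protein, was higher by 0.20 (SE 0.05), though its unpaired SE was 0.38 and its unpaired sign turned without mutant 2 or wild type 1. The NMDA receptor subunit gene Grin1 fell by 0.19 (SE 0.05). Adjusted over the list alone, 2 were higher and 2 lower. Of 26 presynaptic release genes, Syt4 rose by 0.21 and Sv2b fell by 0.25, and of 29 potassium channel genes, Kcna1 fell by 0.46 (SE 0.12). Both of these lists had the same counts adjusted over the list alone, 1 higher and 1 lower for release and 1 lower for channels. Paired, fry's test for change in either direction passed the postsynaptic and channel lists (adjusted p = 0.019 and 0.0084), not the release list (0.18). On all 6 libraries the postsynaptic, release and channel lists did not pass camera, with paired adjusted p = 0.57, 0.13 and 0.067. Unpaired and downward, the postsynaptic list passed without wild type 1 (adjusted p = 0.017) or mutant 3 and wild type 1 together (0.012), and the release list without wild type 2 (0.038) or mutant 3 and wild type 1 together (0.046). The channel list did so without mutant 2 (0.012), wild type 1 (0.019) or mutant 3 and wild type 1 together (0.016), and the postsynaptic list turned upward without mutant 1 (0.99).

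Of 43 axon guidance genes, the paired fit called Draxin, Epha3 and Epha5 higher by 0.26, 0.30 and 0.17 and the semaphorin genes Sema3a and Sema3e lower by 0.31 and 0.49; 38 did not pass, and adjusted over the list alone 6 were higher and 2 lower. The list passed camera with pairing and, on all 6 libraries, not without (adjusted p = 0.021, unpaired 0.14), and not with an estimated correlation (paired adjusted p = 0.65), and it passed unpaired without mutant 1 (adjusted p = 0.0083) or wild type 2 (0.022). Of 56 autism-associated genes, Auts2, Chd2, Dyrk1a, Erbb2ip and Usp7 fell by 0.16 to 0.32 and Shank2 was higher, while 50 did not pass and adjusted over the list alone the counts were the same, 5 lower and 1 higher. Chd2, a chromatin remodeller gene, fell by 0.32 (SE 0.05, adjusted p = 0.00268). That list had a paired adjusted p of 0.22 and an unpaired one of 0.14, and unpaired it passed, downward, without mutant 2 (0.0094), wild type 1 (0.0017) or mutant 3 and wild type 1 together (0.0099), while without wild type 2 its direction turned upward (0.81).

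Among housekeeping groups, 39 cytosolic ribosomal protein genes had a list median of −0.08 and none passed singly. The list passed camera with the preset correlation (adjusted p = 4.4e-05, paired 0.00048), and with an estimated correlation the adjusted p = 0.91, paired 0.71. Of 21 cholesterol synthesis genes, 2 were higher, among them Sc4mol by 0.24 (SE 0.05), and 19 did not pass, with 5 higher adjusted over the list alone. That list had a median of 0.08 and adjusted p = 0.018, paired 0.0029, with 0.91 as the adjusted p with an estimated correlation and 0.65 when also paired. The unpaired call was lost without mutant 2 (adjusted p = 0.12), mutant 3 (0.22), wild type 1 (0.35) or wild type 2 (0.12), and without mutant 3 and wild type 1 together (0.87). Of 20 hypoxia and glycolysis genes only Ndrg1 rose, by 0.24, also adjusted over the list alone, and the list had a paired adjusted p of 0.75.

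Only 3 replication-dependent histone genes were tested, members of near-identical families whose counts are uncertain, and Hist1h1c fell by 1.31 (SE 0.19) and Hist1h2bc by 0.96 (SE 0.20), the same 2 lower adjusted over the list alone. That list passed camera (adjusted p = 0.0061, paired 0.0094) but not with an estimated correlation (adjusted p = 0.81, paired 0.65). The 3 Tshz genes, 2 of them higher with pairing adjusted over the list alone, passed as a list (adjusted p = 0.025, paired 0.036) but not with an estimated correlation (adjusted p = 0.85, paired 0.65). Their unpaired call was lost without mutant 3 (adjusted p = 0.14), wild type 2 (0.3), or mutant 3 and wild type 1 together (0.092). None of 22 neighbours of Tshz3 on chromosome 7 passed, Uri1 having a paired log2 fold change of 0.16, and the list had a paired adjusted p of 0.13.

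**Figure D3:**
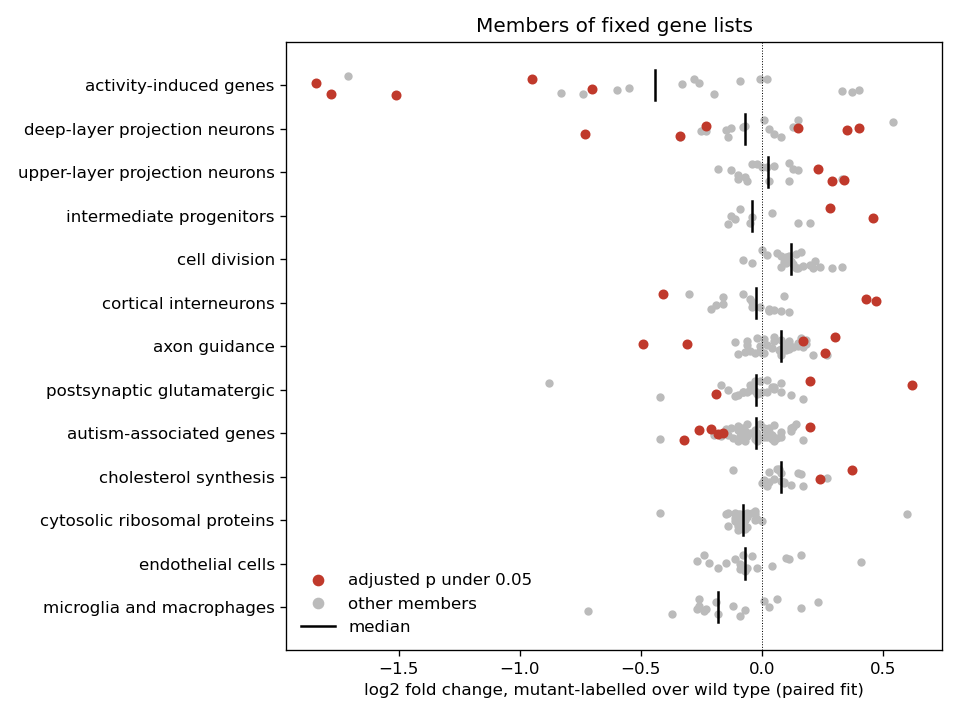
Paired log2 fold change of each tested member of 13 gene lists, mutant-labelled over wild type, with genes past an adjusted p of 0.05 in red, the others in grey, and a black line at each list's median. Activity-induced genes had the lowest median of the lists drawn, −0.44, with Egr1, Egr2, Fosb, Nr4a1 and Ier2 past the threshold, while deep-layer markers had called genes on both sides of 0.

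Markers of tissue around the neocortex showed few changes. Of 19 striatal markers Penk fell by 0.55 (SE 0.12), of 13 hippocampus and hem markers Wnt5a rose by 0.39 (SE 0.10), and none of 11 thalamus markers passed, Prkcd having a paired log2 fold change of 0.11. None of 14 choroid plexus markers passed. Adjusted over the list alone, 1 striatal marker was higher and 5 were lower, and 1 hippocampal marker was higher. These 4 lists had paired adjusted p values of 0.085, 0.46, 0.70 and 0.32. Unpaired, the striatal list passed downward without mutant 1 (0.047) or wild type 3 (0.005), and the choroid plexus list passed downward without mutant 1 (0.0059) and upward without mutant 3 and wild type 1 together (0.022). Of 15 oligodendrocyte lineage markers Gpr17 rose by 0.31 (SE 0.08). Of 16 astrocyte markers the glutamate transporter gene Slc1a2 rose by 0.26 (SE 0.04) and Sparcl1 fell by 0.21 (SE 0.05). Adjusted over the list alone, 1 oligodendrocyte marker was higher, and 1 astrocyte marker was higher and 2 lower. The oligodendrocyte and astrocyte lists had paired adjusted p = 0.71 and 0.74.

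None of 18 pericyte and meninges markers passed singly, Tagln having a paired log2 fold change of −0.63. Their list passed camera with pairing and, on all 6 libraries, not without (adjusted p = 0.033, unpaired 0.25; paired adjusted p = 0.71 with an estimated correlation), and its medians in pairs 1, 2 and 3 were −0.21, −0.88 and 0.23. Unpaired it passed without mutant 1 (adjusted p = 0.0027) or wild type 3 (6.5e-06), and its direction turned upward without wild type 1 (0.68) and without mutant 3 and wild type 1 together (0.15). None of 17 microglia and macrophage markers passed singly, C1qa having a paired log2 fold change of −0.26, and that list passed with pairing (adjusted p = 0.034, unpaired 0.14; paired adjusted p = 0.65 with an estimated correlation), or unpaired without mutant 1 (adjusted p = 8.7e-05) or wild type 3 (0.011), and its direction turned upward without mutant 3 and wild type 1 together (0.62). None of 19 endothelial and 4 erythroid markers passed, Sox18 having a paired log2 fold change of 0.41, and their lists had paired adjusted p = 0.22 and 0.18. Unpaired, the endothelial list passed downward without mutant 1 (0.042) and upward without mutant 3 and wild type 1 together (0.021), and the erythroid list passed upward without wild type 1 (0.048) or mutant 3 and wild type 1 together (0.0099).

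The sex makeup of the pools differed between libraries. The sum of 4 Y-linked genes was 57.0, 124 and 0 CPM in mutant libraries 1 to 3 and 167, 73.6 and 111 CPM in wild-type libraries 1 to 3, so that mutant-labelled libraries were lower in pairs 1 and 3 and higher in pair 2. Xist had 18 counts in wild type 1, and no Y-linked read was counted in mutant 3. The list of Y-linked genes and Xist did not pass (paired adjusted p = 0.31), though unpaired it did without mutant 2 (0.033). Without those 2 single-sex pools, 4 libraries remained and edgeR called 0 genes, with 587 at an unadjusted p under 0.05 and 21 called by DESeq2. All 11 genes called from 6 libraries kept their direction. That is no separate evidence, because the 4 libraries are among those that picked the genes.

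Across all 31 lists tested, camera with the preset correlation called 6 without pairing and 9 with it. With an estimated correlation 0 lists passed in either fit, 1 having an unadjusted p under 0.05 in each. The fry test of movement in 1 direction also passed 0 lists, with 4 unadjusted and 9 when paired, and its test for change in either direction passed 2 lists unpaired, the deep-layer and activity lists, and 22 paired. Egr1 and Hs3st4 were the list members called without pairing over all genes. Adjusted over the list alone without pairing, calls beyond the deep-layer and activity lists were few. These were 1 Tshz gene, 1 interneuron marker, 1 astrocyte marker, 1 postsynaptic gene and 1 hypoxia gene higher, and 1 subplate marker, 1 interneuron marker and 2 histones lower. Lists for which no count adjusted over the list alone is given had 0 such calls in both fits. Several named genes overlap an annotated gene on the other strand, among them Tshz2, Lrrtm1, Acvr1c, Ramp3, Grin1, Sv2b, Draxin, Auts2 and Gpr17. Whether counting used strand is not given in the sources used here, so reads of such partners cannot be told apart.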

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

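The tests with the 2 single-sex pools left out, with a Y-linked covariate, and all alternatives of the paired fit were chosen after the data were seen. Of 104 named genes, 99 kept their direction in every one of 19 settings. Those settings reuse the libraries that picked many of these genes, so the kept direction is weak evidence. The counts of 7 higher and 4 lower genes became 63 and 43 with DESeq2's test and 11 and 9 without a filter, and 8 were lower with upper-quartile scaling. They became 288 and 218 with the replicate block, 0 and 0 without the single-sex pools, 1 and 2 with the Y-linked covariate, and 419 and 477 with both the block and that covariate. The fit with both leaves 1 residual degree of freedom, so its counts and adjusted p-values are weak evidence. Leaving out 1 library at a time gave 1 to 21 higher and 2 to 14 lower genes, with Tshz3 at 0.12 to 0.22 and 4 to 12 lists. DESeq2's scaling, limma-voom, the stricter filter, thinned counts and leaving out haemoglobin genes stayed within 1.5 times of both counts, and the 11 genes all passed with DESeq2's test and with the block. Most genes that the block added are given in the report only as counts, and so are some of the lists that it added in fry's test for change in either direction. The paired counts became 112 and 76 with DESeq2's test and 66 and 67 with a log2 fold threshold of 0.5, and 188 higher with limma-voom and 460 higher without a filter. Without pair 1 there were 141 higher, without pair 2 1119 and 755, and without pair 3 35 and 27, and 11 of the 11 genes called without pairing passed in each of those. Pair 2 is the pair in which the mutant-labelled pool had more Y-linked RNA, so that without it genotype and sex makeup ran together. Tshz3 stayed above 0 throughout, at 0.17 with the block (adjusted p = 0.0525) and at 0.17 with the block and the Y-linked covariate (adjusted p = 0.0428, the only one of its settings past the threshold; the others ranged from 0.0525 to 1). The 6 lists became 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, 0 with the block and fry, and 11 without the single-sex pools. Signs turned, none of them called without pairing, for Tshz1 (0 to 0.14 with single libraries left out), Shank2 (−0.15 to 0.59), Tbr1 (−0.04 to 0.11, and −0.04 without the single-sex pools), Cux2 (−0.05 to 0.28, and −0.05 without the single-sex pools) and Meg3 (−0.02 without the single-sex pools). The cause was not tested for any of these, except that fewer libraries leave less power. The median log2 fold change of all tested genes lay between −0.008 and −0.006 under every scaling. In simulated data that held pair effects, changes near 1.3-fold were mostly out of reach without pairing at this depth and n = 3.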

Other observations

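Genes outside the fixed lists, picked here after their values were seen, passed with pairing and not without it. The neurotrophin receptor genes Ntrk2 and Ntrk3 fell by 0.29 (SE 0.04) and 0.30 (SE 0.05) on the log2 scale, beside the drop of Ngfr. Ntsr1, a marker of corticothalamic neurons, fell by 0.25 (SE 0.05), and Timp3, an inhibitor of matrix proteases, fell by 0.54 (SE 0.06). The transcription factor genes Bhlhe22 and Prdm8, which encode partners in a repressor complex, rose by 0.33 (SE 0.05) and 0.45 (SE 0.07). The somatostatin receptor gene Sstr1 rose by 0.62 (SE 0.06), from 50.2 ± 7.11 to 77.0 ± 4.26 CPM (n = 3 each). Wnt2, a Wnt ligand gene, rose by 1.71 (SE 0.38) from a low 0.284 ± 0.0426 CPM and Wnt7b, another, fell by 0.18 (SE 0.05), beside the rise of Wnt5a.

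The share of called genes near Tshz3 did not differ from that elsewhere by more than the test can tell. Within 5 Mb of Tshz3, 2 of 36 tested genes passed with pairing, 1600014C10Rik, which was higher, and Gpi1, which fell by 0.22. That is 5.56%, against 3.46% of 14434 genes elsewhere (Fisher's exact test, two-sided, p = 0.356).

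For the patterns weighed next, the tests of swapped labels, of the mutated allele, of sex, of vascular cells, of nuclear RNA and of the paired splits were chosen after the result was seen.

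Tshz3 counts were not lower in mutant-labelled libraries. If the mutation lowers the gene-level count, mixed-up labels would still leave some of the 6 libraries low, and the lowest held 0.79 of the highest library's CPM. If it does not lower that count, the ratio says nothing about the labels. Reads borrowed from genes with like sequence are argued against, since 0.59% of the 30-base words of Tshz3 transcripts recur in transcripts of other genes. Words were compared in the same orientation only. Reads of a transcript antisense to Tshz3 are therefore not addressed, because the strand setting of the counting is not given. An allele that still makes RNA over the counted exons may explain the value of 0.17, and it cannot be told apart from other causes here because the table has no counts per exon.

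Of 20 activity-induced genes 5 were called lower with pairing and Egr1 alone without it, and the list's call was lost with an estimated correlation (adjusted p = 0.81, paired 0.65) and with fry (0.13 in both fits). Sex makeup of the pools would have turned the sign in pair 2, where the mutant-labelled pool had more Y-linked RNA, but the list's median there was −0.73. Fewer vascular or meningeal cells would have lowered those markers in each pair. Their joint medians were −0.14, −0.21 and 0.07 in pairs 1, 2 and 3, against −0.17, −0.73 and −0.55 for the activity list. The pericyte and meninges list alone had medians of −0.21, −0.88 and 0.23. Pair 3 argues against such cells as the whole cause, and pairs 1 and 2 leave them open. A difference in neuronal activity before birth may underlie the pattern, and so may a difference in handling between dissections. No value in the table separates these.

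Transcripts that hold microRNA genes drew attention because A930011O12Rik (Mir124a-1hg) rose by 1.26 and Mir17hg by 0.72 with pairing, together with Dgcr8, which encodes a partner of the enzyme that cuts primary microRNA transcripts, by 0.39, while Mirlet7b and Mirlet7c-2 had log2 fold changes of −2.81 and −3.63 from wild-type levels of 1.49 ± 0.824 and 1.63 ± 0.659 CPM. Of 19 microRNA rows tested those were the 2 called lower, 1 was called higher (Mir3064, 0.54), and the median was −0.14. The 2 lower rows start at 85707319 and 85706603 on chromosome 15, so they may not be separate changes. Such short rows can lie inside longer transcripts, so their counts are uncertain and may not measure mature microRNA. Less cleavage of transcripts that hold microRNA genes could raise them all. The median of the 14 tested hosts was only 0.05, at percentile 91 of 10000 expression-matched random lists. Without the 2 that prompted the question it was 0.03, at percentile 78.8. A330023F24Rik, the host of Mir29b-2 and Mir29c, fell by 0.76. More nuclear RNA is argued against as the cause of the rises of A930011O12Rik and Mir17hg by 6 nuclear long non-coding RNAs, whose median was −0.15 and which ranged from −0.56 for Neat1 to 0.05 for Meg3, itself 1 of the 14 hosts, with Malat1 at −0.19. The cleavage hypothesis cannot be told apart from changes in single genes with 14 hosts.

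Other divisions of the libraries bear on how firmly the counts stand. Of the 10 ways to split the 6 libraries into 3 and 3, 2 gave at least the 11 genes of the real split, itself included, and the highest other count was 35. That count came from mutant 1, wild type 1 and wild type 2 against the rest, and points to a structure of the samples whose source was not tested. The other split that keeps pairs 1 and 3 whole called 0 genes. Among the 4 splits that part every pair, 1 reached 506 genes in the paired fit, the real one, and the highest other count was 0. For lists, 5 of the 10 splits reached the real count of 6, with 16 as the highest other, and with pairing 1 of the 4 reached the real count of 9, with 8 as the highest other. With 10 or 4 splits no share under 0.05 can be had.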
